A study of Mus musculus with 12 samples.

How the data were processed

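The study sequenced RNA from brain sections of wild-type mice kept for 5 hours in artificial cerebrospinal fluid (aCSF) or in aCSF with L-fucose, with 6 libraries per group. Per the labels' protocols, RNA was extracted with a column kit, messenger RNA was taken up on poly-T beads, and fragmented RNA was primed with random hexamers for Illumina sequencing. The submitters' processing notes list Trimmomatic 0.39, HISAT2 2.2.1, featureCounts 2.0.3, DESeq2 2.11.40.8 and the mouse build mm10. The annotation release, the strand setting of the counting and any filter are not given in the sources used here.

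The authors deposited 1 table of 56923 Ensembl gene identifiers by 12 libraries, whose values are a normalized signal, gene read counts divided by 1 size factor per library. This was found from the values: in every library 100% of values were whole multiples of the value of 1 read, within a tolerance of 0.01 reads, and the largest deviation was 0.000424. Size factors recomputed from the recovered reads by the median-of-ratios method of DESeq2 differed from those in the table by at most 3.51e-10. Reads were recovered by dividing each value by the value of 1 read, and their sums gave the depth. The design had been written for raw counts, with edgeR, TMM factors and the default edgeR filter as the main test. Since the deposited signal is normalized, limma with the filter given below became the main test. This choice was made after the values were seen. The planned edgeR fit was run on the recovered reads and is given as an alternative.

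Identifiers were matched to symbols and to positions in the GENCODE M21 annotation of GRCm38, the same assembly as mm10. A symbol was found for 52073 identifiers and not for 4850, of which 2142 began with ENSMUSG00002, a kind of identifier with 0 matches. Because rows named for genes that every brain cell transcribes lay near 0, the position each row had counted was checked. In windows of 80 neighbouring rows, moved in steps of 20 rows, the mean level over the 12 libraries was correlated with the presence of protein-coding exons after displacing the row positions by up to 600 kb either way, in steps of 500 bp. A row was called in register where every window covering it matched best within 1000 bp of no displacement and the region held at least 120 rows. The treatment groups did not enter this rule, but it was set after the data were seen. The minimum of 120 rows was chosen on simulated levels, because shorter regions had included displaced rows there. On that same simulation, 82.3% of 17929 undisplaced rows and 0 of 34107 displaced rows were called in register, so the count of 0 is not an independent error rate. Each simulated chromosome had a single constant displacement or none, and displacements of a few kb were not simulated. Whether rows with small or changing displacements could still be called in register was not checked. No row was renamed and no coordinate was converted. A row outside the regions in register is still an interval counted alike in all libraries, so its test between groups holds, but its name may not tell which transcript was counted.

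Rows with a value of at least 10 in at least 6 libraries were tested, which left 10787. limma 3.58.1 was fitted to log2(value + 1) with the treatment group as the sole term and an intensity trend in the variance. P-values were two-sided, were adjusted by the Benjamini-Hochberg method over all tested rows, and had a threshold of 0.05. Fold changes are L-fucose minus aCSF on the log2(value + 1) scale, which understates the change of low rows, and intervals are 95% confidence intervals from limma. A further adjustment over the 347 tested rows in register alone was added after the data were seen. Gene lists were tested with camera at a preset correlation of 0.01, two-sided, if at least 3 rows were tested. Measures of 1 value per library were compared by an exact permutation test over all regroupings. The computations used R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, sva 3.50.0, Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.

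The lists, the use of camera, the rule for named genes and most alternatives were fixed before the data were examined. The main limma test and its filter were not, and camera, planned on log2 CPM, was run on the limma values. The rule for named genes took the 10 highest-ranked genes each way among those past the threshold, with the 5 of largest change each way. If fewer than 5 passed, it took the 5 with the smallest p each way. It added every measured gene of the fucose list and up to 4 members of every other list. After the values were seen, the members of the other lists were restricted to rows in register and mitochondrial rows, because other names may not say what was counted. The 5 higher and 10 lower rows in register with the smallest p were added at the same point. Predicted gene models were left out, as fixed.

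Alternatives were edgeR with TMM, RLE or upper-quartile factors, limma-voom, DESeq2, no filter, a filter of 1 CPM in 6 libraries, a block for the replicate number, 1 surrogate variable, a sex term, other thresholds, pseudocounts of 0.5 and 5, windows of 60 and 120 rows, and each library left out in turn. The pseudocounts, the limma block and the windows were chosen after seeing the data. So were the adjustment over rows in register, the fits without aCSF 5 and 6, and the main limma fit with its filter. The edgeR fit with TMM had been planned as the main test. The independent filtering of DESeq2 was set for an adjusted p of 0.05 after its default of 0.1 had been run, and both are reported.

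The test was checked on simulated reads with 200 changed rows, drawn from the means, depths and dispersions of these libraries. Of rows changed 1.5-fold, 2-fold and 4-fold, limma recovered 22.4%, 40.3% and 81.8% with 6 false calls among 10393 rows, and edgeR recovered 22.4%, 43.3% and 86.4% with 5 false calls among 10402 rows. Totals of 9191687 to 18563078 reads per library set the counting precision. Sequenced reads carried no molecular identifiers, so depth describes reads, not molecules. No 2 columns of the table held the same values. The labels do not say that the libraries come from separate animals, so p-values measure only the spread between these samples, which may be technical.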

Results

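RNA was sequenced from brain sections of wild-type mice after 5 hours in aCSF, the salt solution that keeps living brain slices supplied with ions and glucose, or in aCSF with added L-fucose, a deoxy sugar that cells attach to glycoproteins and glycolipids. Each condition had 6 libraries, named here by group and replicate number. Library totals ran from 9191687 reads in aCSF 4 to 18563078 in L-fucose 2, with a median of 11168285. The table held 56923 rows, 1 per Ensembl gene identifier, and 27688 of them were at 0 in every library. Values are normalized read counts, the reads of a row divided by the size factor of its library.

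Rows named for several abundant genes did not hold the level expected of them. Rows named for Actb, Eef1a1 and Snap25, whose transcripts are abundant in brain, had means of 19.5, 0.197 and 0.616 normalized reads over the 12 libraries, and Ttr was at 0 in each. The row named for Cd3e, a T cell receptor component, had a mean of 2379. Row positions were displaced along the genome in search of the best match between levels and protein-coding exons, and the highest correlation lay over 1000 bp from none in 2444 of 2527 windows, or 96.7%. For a single window this is the highest of many correlations, in some windows all near 0, and does not show that its levels followed exons there. Over whole chromosomes, the displacement that fitted best was none for 9 of 21, and it was -164 kb over chromosome 10, -109.5 kb over chromosome 11 and -180 kb over chromosome 16. In 83 windows the best fit was within 1000 bp of none. Stretches of at least 120 rows where every window fitted best within this tolerance made up 4 regions, on chromosome 4 from 3.10 to 40.97 Mb and from 45.14 to 55.47 Mb, on chromosome 6 from 3.07 to 23.16 Mb and on chromosome 15 from 8.92 to 36.73 Mb in GRCm38. These regions in register held 1080 rows, of which 347 were tested. Genes abundant in neurons were high there, with Basp1, a growth cone protein, at 23320 ± 2052 (SD over 12 libraries) and Gabbr2, a subunit of the metabotropic GABA receptor, at 10730 ± 1102. The regions were chosen because levels there match exons, so high values of such genes are no separate check of the names. Mitochondrial rows separated messenger and ribosomal RNA from transfer RNA best with a shift of 0 rows. Genes are described below as such where their rows lie in register or on the mitochondrial genome, whose rows were not checked against displaced positions.

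**Figure D1:**
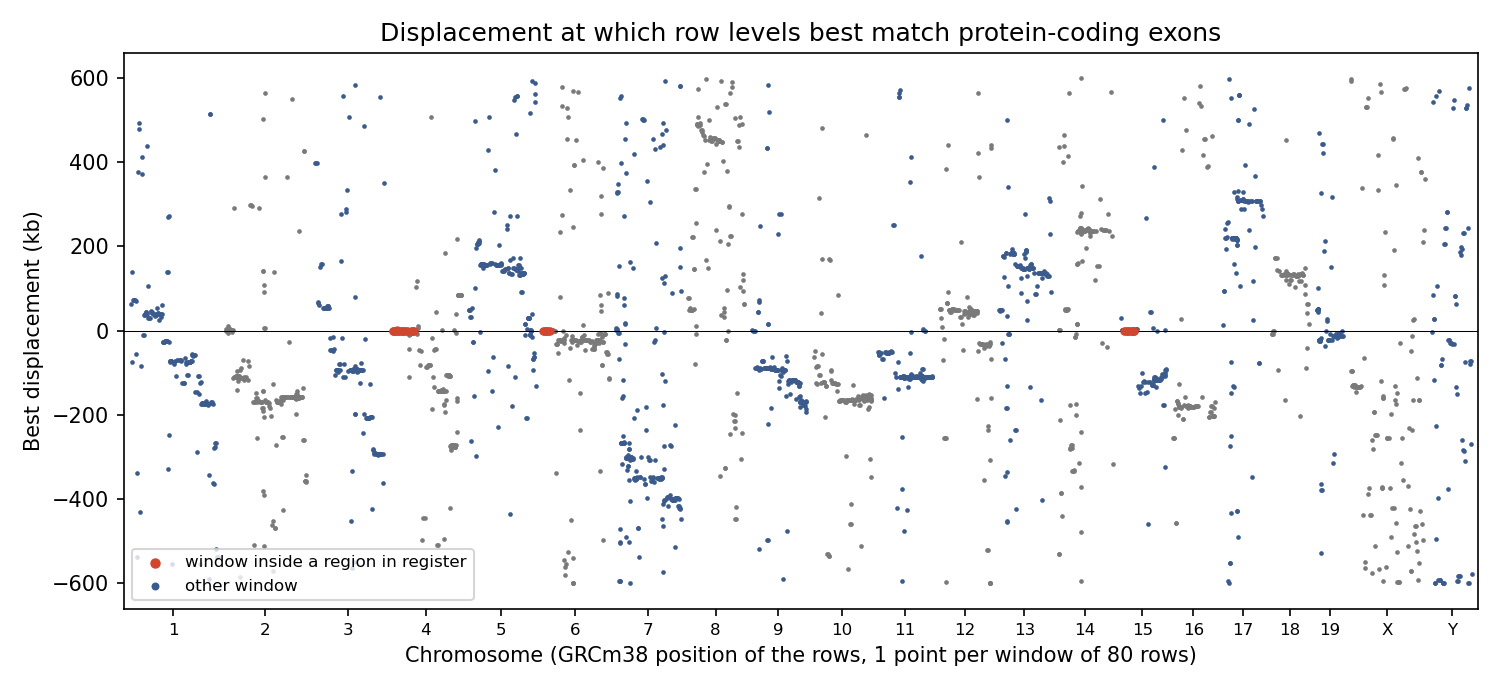
Each point is a window of 80 neighbouring rows, placed by GRCm38 chromosome on the horizontal axis, and the vertical axis gives the displacement in kb at which row levels best matched protein-coding exons. Red points mark windows inside the 4 regions in register, and blue and grey points mark other windows on alternating chromosomes, where windows without a clear match at any displacement are plotted too. The highest correlation lay over 1000 bp from 0 in 2444 of all 2527 windows.

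The comparison of L-fucose with aCSF asks which transcripts differ after 5 hours with the sugar. Among the genes in register, Gabrr2, which encodes a rho subunit of ionotropic GABA receptors, was lower in L-fucose, at 26.4 ± 2.77 normalized reads against 81.4 ± 33.6 in aCSF (SD, n = 6 each). Its log2 fold change was -1.51 with a standard error of 0.29 and an interval from -2.12 to -0.90. The L-fucose libraries lay between 22.7 and 29.35 and the aCSF libraries between 50.42 and 144.4, without overlap. Abca1, the transporter that loads cholesterol onto apolipoproteins, had 817 ± 100.4 in L-fucose against 1144 ± 174 in aCSF, a log2 fold change of -0.48 with a standard error of 0.12. Penk, the precursor of the enkephalin opioid peptides, had 9059 ± 1958 in L-fucose against 6171 ± 2192 in aCSF, a log2 fold change of 0.61 with a standard error of 0.20. Gabrr2 (ENSMUSG00000023267) lies on chromosome 4 from 33062999 to 33095865, Abca1 (ENSMUSG00000015243) from 53030787 to 53159895 and Penk (ENSMUSG00000045573) from 4133531 to 4138819, all in GRCm38.

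With limma, 0 of 10787 rows were higher and 0 were lower at the adjusted threshold, and the smallest adjusted p was 0.498, that of Gabrr2, Abca1 and other rows named below. At an unadjusted p under 0.05 there were 643 rows, or 5.96%, of which 342 were higher and 301 lower, and without aCSF 5 and 6 there were 1177 of 10425 rows, with 0 past the adjusted threshold (smallest adjusted p 0.1244). edgeR with TMM factors and limma-voom also gave 0 rows, with 604 and 632 of 10771 rows at an unadjusted p under 0.05. DESeq2, which tested 29080 rows, gave 1, Gabrr2, with an adjusted p of 0.003114. Its 1054 rows at an unadjusted p under 0.05 were a smaller share of the rows tested. Adjusted over the 347 rows in register alone, a choice made after the data were seen, Gabrr2 passed with a limma adjusted p of 0.0161, and Abca1 (0.0949) and Penk (0.220) did not. This Gabrr2 call ended without aCSF 4 (log2 fold change -1.46, adjusted p 0.0628 in limma) and without aCSF 6 (-1.33, 0.0534), and with a block for the replicate number in edgeR (-1.55, 0.0574) and limma (-1.51, 0.0652), but not with this block in DESeq2 (-1.55, 0.00407), where the adjusted p over all rows was 0.0528. Penk passed without aCSF 5 and 6, at a log2 fold change of 0.88 and an adjusted p of 0.0180 in limma. These libraries held the highest aCSF values of Penk, 7818 and 9043, so leaving them out by itself widens the difference.

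**Figure D2:**
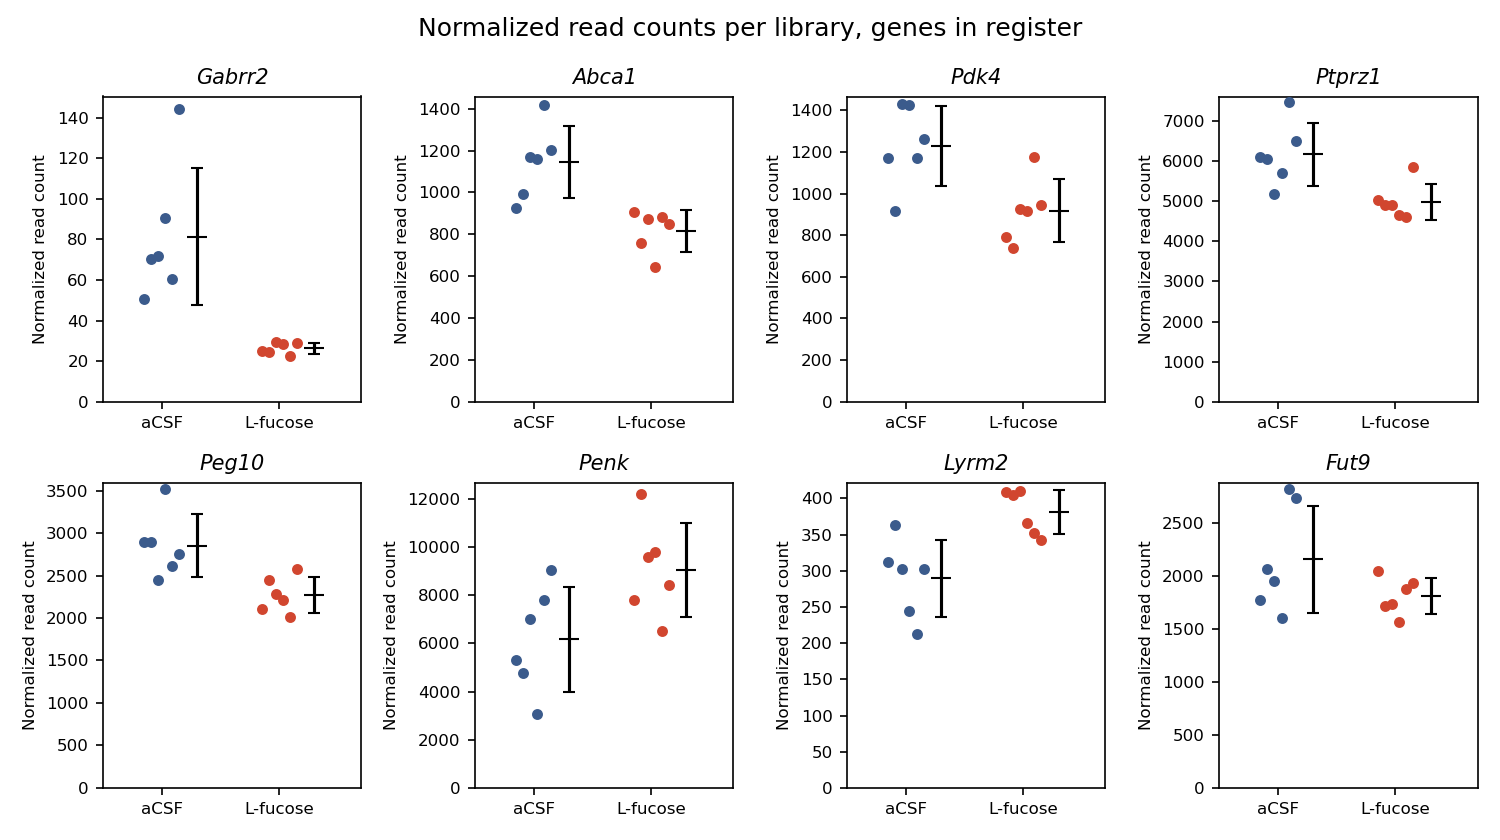
Normalized read counts of 8 genes in register, with 1 point per library (6 aCSF in blue, 6 L-fucose in red) and the mean ± SD beside each group, on linear vertical axes that start at 0. The groups do not overlap for Gabrr2, with aCSF libraries from 50.42 to 144.4 and L-fucose libraries from 22.7 to 29.35, nor for Abca1, and they overlap for the other genes plotted.

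Of the 347 rows in register, 29 had an unadjusted p under 0.05, 24 with a negative and 5 with a positive fold change. None but Gabrr2 passed the adjustment over these rows in the main limma fit. Genes with negative values and the smallest p included Spef2 and Cfap206, components of the axoneme of motile cilia and flagella, at -1.30 (interval -2.06 to -0.53) and -0.76 (-1.22 to -0.30). Others were Bach2, a transcriptional repressor, at -0.56, Capsl at -0.80 and Rai14, an actin-binding protein, at -0.46. Pdk4, the kinase that inhibits pyruvate dehydrogenase, was at -0.42 (-0.68 to -0.16), the imprinted gene Peg10 at -0.32 and Ptprz1, a receptor phosphatase of glia, at -0.30. In each of these genes except Bach2, all 6 L-fucose libraries were below the aCSF median, and Bach2 was below it in 5 libraries. On the positive side were Lyrm2 at 0.41 (0.12 to 0.70), the potassium channel subunit Kcns2 at 0.27, the mitochondrial aldehyde dehydrogenase Aldh1b1 at 0.31 and the ubiquitin ligase March11 at 0.28 (-0.02 to 0.57), each with 6 of 6 L-fucose libraries above the aCSF median. The median log2 fold change in register was -0.05, and for 279 rows, or 80.4%, the interval excluded a change of 1 log2 unit either way.

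**Figure D3:**
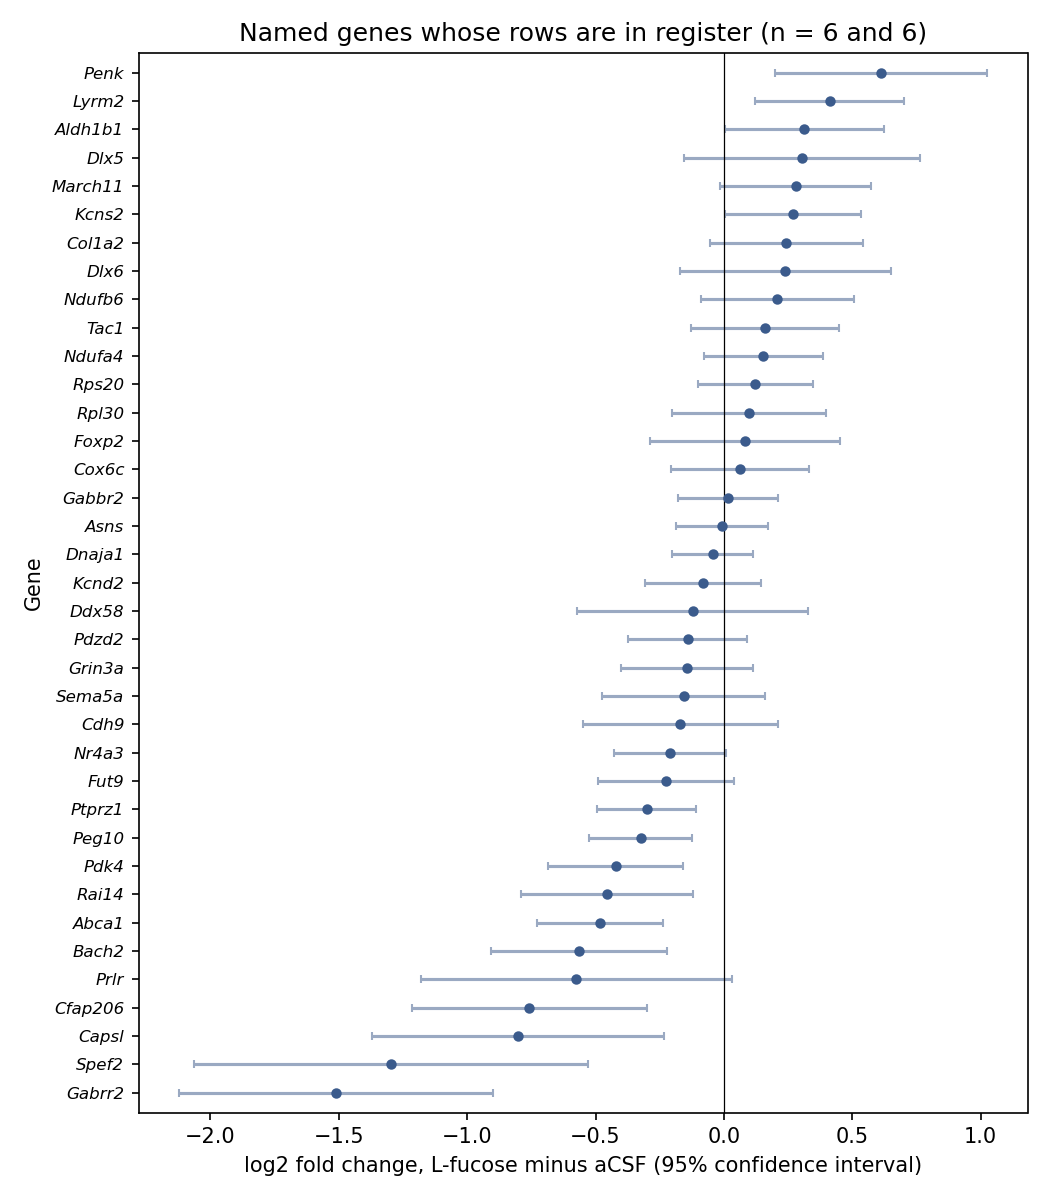
Log2 fold changes, L-fucose minus aCSF, of the named genes in register (points) with 95% confidence intervals from limma (bars), 6 libraries per group, in order of fold change. Gabrr2 at -1.51 lies farthest from 0 and Penk at 0.61 is the highest. Apart from Gabrr2, no gene passed the adjusted threshold over the rows in register in the main limma fit, with the treatment group as the sole term.

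The fucose metabolism and fucosylation list was the one nearest to the treatment. Fut9, the fucosyltransferase that makes the Lewis X antigen in brain (ENSMUSG00000055373, chromosome 4 from 25609332 to 25800244), was its sole member in register. Fut9 had 1813 ± 174 in L-fucose and 2159 ± 507 in aCSF, a log2 fold change of -0.23 with an interval from -0.49 to 0.04, so a change of that size was not told apart from the spread of the libraries (limma adjusted p 0.848). The 2 highest aCSF values were those of aCSF 5 and 6, and without these the fold change was -0.03. The list had 19 rows in the table and 11 tested, 5 with positive and 6 with negative fold changes between -0.53 and 0.53 and a median of -0.07 (camera adjusted p 0.731). With limma, 0 members passed over all rows and 0 passed adjusted over the list alone. The other 10 tested rows, not in register, carried the names Fuk at 0.10, Fut7 at -0.07, Slc35c2 at 0.04, Fut2 at -0.37, Fut1 at 0.19, Fut11 at -0.34, Pofut1 at 0.53, Pofut2 at -0.14, Fuca2 at -0.53 and Fuom at 0.11 (-0.14 in edgeR with TMM factors). Their values without aCSF 5 and 6 ran from -1.42 for Fuca2 to 0.44 for Pofut1, with Slc35c2 at 0.26, Fut2 at -0.20, Fuom at -0.66, Fut11 at -0.54, Pofut2 at -0.03 and Fut1 at -0.0083. What these rows counted may not be what their names say.

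Grin3a, an NMDA receptor subunit, was at -0.14, Gabbr2 at 0.02 and Kcnd2, an A-type potassium channel, at -0.08, each with an interval that included 0, unlike those of Gabrr2 and Kcns2. These are the sole members in register of the glutamate receptor, GABA and ion channel lists, which are therefore not tested as lists of those genes. Of the immediate early genes, Nr4a3 was in register, at 3906 ± 614 in L-fucose and 4500 ± 543 in aCSF, a log2 fold change of -0.21 (interval -0.43 to 0.01). Tac1, the substance P precursor, was at 0.16. In the main limma fit of all 12 libraries, Penk and Pdk4 did not pass over the rows in register. Penk did pass there in limma with 1 surrogate variable added (log2 fold change 0.70, adjusted p 0.0221). The passing of Penk and Pdk4 in an adjustment over single lists is not used here, since most rows of those lists are not in register. Pdk4 was at -0.42 and Penk, whose highest aCSF values were in these libraries, at 0.88 without aCSF 5 and 6.

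The genes named next, of respiration, translation and stress, had intervals that included 0 with all 12 libraries. The respiratory chain subunits Ndufa4, Ndufb6 and Cox6c were at 0.15, 0.21 and 0.06, and the ribosomal proteins Rps20 and Rpl30 at 0.12 and 0.10. These were at 0.23, 0.30, 0.20, 0.20 and 0.24 without aCSF 5 and 6. The co-chaperone Dnaja1 was at -0.04 (interval -0.20 to 0.11), the asparagine synthetase gene Asns at -0.01 (-0.19 to 0.17; 0.0068 in edgeR with upper-quartile factors) and Ddx58, a sensor of viral RNA, at -0.12 (-0.27 without aCSF 5 and 6). Ndufb6, Rpl30, Penk and Dnaja1 share 39.0%, 24.8%, 14.3% and 10.8% of their exonic bases with neighbouring genes, mostly on the other strand, so their values are uncertain without a stated strand setting. Exons were shared in 11 of the 37 named genes in register. Rps20, Rpl30 and Cox6c also belong to gene families with processed copies elsewhere in the genome.

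Markers of cell types and regions were covered in register by few genes. Dlx5 and Dlx6, transcription factors of forebrain interneurons, were at 0.30 (interval -0.15 to 0.76) and 0.24, Foxp2, a marker of deep cortical layers, at 0.08, Penk and Tac1, which are also markers of the striatum, at 0.61 and 0.16, Col1a2, a fibroblast collagen, at 0.24 and Prlr, high in choroid plexus, at -0.57 (-1.18 to 0.03). With aCSF 5 and 6 left out, Dlx5 was at 0.51, Dlx6 at 0.38, Foxp2 at 0.30, Tac1 at 0.27, Penk at 0.88 and Prlr at -0.75. The dentate gyrus list had Pdzd2 at -0.14, Sema5a at -0.16 and Cdh9 at -0.17. Of the 46 lists, 43 were tested and 0 passed with camera (smallest adjusted p 0.366; 0.739 with an estimated correlation), and 3 had an unadjusted p under 0.05. These were oligodendrocytes (10 rows, all with negative values, median -0.24), synaptic adhesion (15 rows, median 0.15) and mural cells (8 rows, median 0.21), and none of their rows is in register. Without aCSF 4 the oligodendrocyte list passed camera at 0.0379 (adjusted p = 0.302 with an estimated correlation). The lists held 470 tested rows, of which 24 were in register and 13 mitochondrial. The lists not named here had adjusted p between 0.6386 and 0.967 with camera, apart from 2 with fewer than 3 tested rows and the sex-linked genes, a check that was not among the lists adjusted for. In 6 lists the median and the camera direction differed in sign, among them the mitochondrial list.

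Mitochondrial transcripts took 35.8 ± 2.59% of the counted reads in L-fucose and 36.5 ± 6.16% in aCSF (SD, n = 6 each). The difference was -0.723 percentage points (exact permutation p = 0.771, also after adjustment over 3 measures). Reads that no row counted are not included, so the share among all sequenced reads is not known. All 13 mitochondrial messenger RNAs were tested and 0 passed in limma, with a median log2 fold change of -0.01. mt-Nd5, a subunit of complex I, was at -0.12 with 149600 ± 22140 in L-fucose, and mt-Co2, a subunit of cytochrome c oxidase, was at 0.63 (interval 0.14 to 1.12; limma adjusted p 0.827), with 6 of 6 L-fucose libraries above the aCSF median. mt-Atp6 was at 0.65 (-0.01 to 1.32) and mt-Nd4l at 0.26. Without L-fucose 6, the highest library for both, mt-Co2 was at 0.39 and mt-Atp6 at 0.43. In L-fucose, mt-Co2 had 8582 ± 4522 and mt-Atp6 4043 ± 2136, below mt-Nd5. The cause of this difference was not tested, so these values and their fold changes may not measure the levels of the transcripts. Without aCSF 5 and 6 the difference in mitochondrial share was 2.72 percentage points (exact permutation p = 0.252, n = 4 and 6), and mt-Co2 was at 0.87 and mt-Atp6 at 1.03. The list of messenger RNAs then passed camera as higher at 9.77e-05 (adjusted p = 0.879 with an estimated correlation). As aCSF 5 and 6 had the highest mitochondrial shares, leaving them out by itself moves these values up.

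aCSF 5 and aCSF 6 stood apart from the other libraries. Their mitochondrial shares were 41.9% and 44.8%, the highest of the 12, and they had the fewest rows above 0, 14340 and 14856, against 16514 or more elsewhere. The first principal component, 24.4% of the variance, placed them at 82.5 and 57.5, L-fucose 4 at 21.7 and the others between -32.2 and -2.49. Rows above 0 averaged 17380 ± 884 in L-fucose and 16240 ± 1324 in aCSF (exact permutation p = 0.139; 0.250 adjusted over 3 measures). Without aCSF 5 and 6, the fold changes of mt-Nd5, Kcnd2, Sema5a and Asns turned positive, at 0.094, 0.037, 0.036 and 0.056, and that of Fut9 was -0.027. The rows named for the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were high in 3 libraries of each group, aCSF 1, 4 and 5 and L-fucose 1, 3 and 5, with Ddx3y at 1184 or more there and at most 6.082 in the others. The row named Xist, at 273.7 to 489.3 in all 12 libraries, did not follow this division, and none of these rows is in register.

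Rows with the smallest p over the whole table did not pass limma, and some of those that the fixed rule selects are described here. The rows labelled Lrrc26, Zfp286, Prtn3, Tesc and Ccl5 had positive fold changes of 0.86, 0.76, 0.45, 0.60 and 0.48, and those labelled Atl2 and Sema3c had negative ones of -0.70 and -1.40, each with 6 of 6 L-fucose libraries on that side of the aCSF median. Adjusted p was 0.498 for all of these except Sema3c, at 0.601. None of these rows is in register, so their names may not say which transcripts were counted.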

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

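The tests of why named rows lie near 0 were chosen after that pattern was seen, and all but the one on held-out rows after their own result. Of 124 groups of 6 values examined (named genes and library measures), 6 held a library far from the other 5, and chance alone gives this in about 5% of groups. mt-Co2 was 17750 in L-fucose 6 against 6053 to 7709 in the other L-fucose libraries, and the mt-Co2 log2 fold change without it was 0.39. mt-Atp6 was 8068 in L-fucose 6 against 2049 to 4168. Ptprz1 was 5845 in L-fucose 6 against 4603 to 5025. Aldh1b1 was 367.7 in L-fucose 4 against 239.3 to 281.3. Nr4a3, an immediate early gene, was 5087 in L-fucose 1 against 3397 to 3943. Cdh9, a cadherin, was 375.8 in aCSF 5 against 168.9 to 237.4.

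Rows labelled with abundant brain genes lay near 0, Eef1a1 at a mean of 0.197 and Ttr at 0. A shift of all names by some number of rows is argued against, since the mitochondrial rows separated messenger and ribosomal RNA from transfer RNA best at a shift of 0 rows. Row positions displaced from the genes, by an amount that stays the same along stretches of a chromosome, may account for it: neighbouring windows without a shared row had the same displacement in 13.43% of cases, against 0.676% after shuffling. That the libraries held little of these transcripts is argued against as the whole cause: 5 chromosomes (3, 10, 11, 16 and 17) matched exons better at a displacement than at none by over 0.1 in correlation with a 95% interval above 0, against 0 of 21 simulated chromosomes with rows in place and 30% of genes transcribed. The interval keeps the displacement fixed at the best of those tried, so it does not allow for that choice. Correlations at no displacement were also higher in that simulation than in the data, at 0.43 against 0.23 on chromosome 3 and 0.43 against 0.19 on chromosome 16. The simulation is therefore not a matched comparison, and this explanation is not excluded. For single windows and rows, that the libraries held little of these transcripts stays open. In held-out rows the median gain in correlation at the displacement chosen on the other rows was -0.0199. This was above the -0.5193 of simulated undisplaced chromosomes, but those were not simulated with few genes transcribed. Simulated displaced chromosomes gave -0.1205, also negative. A negative gain therefore does not tell displaced rows from rows in place, and this test cannot decide. Of 88 ribosomal protein rows outside the regions in register 29.55% were tested, and the regions themselves hold 2 such rows, both tested, too few to compare. No biological explanation was tested. The submitters' notes list the build mm10, but which annotation was paired with the reads is not given in the sources used here.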

How the results depend on the processing

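Counts over all rows were 0 each way in limma and in 14 of 18 other fits, and in 12 of 12 fits without 1 library, where 426 to 771 rows had an unadjusted p under 0.05 and the smallest adjusted p ran from 0.0718 to 0.958. Rows at an unadjusted p under 0.05 were 643 with all libraries, 1177 of 10425 without aCSF 5 and 6, 905 of 10229 without L-fucose 4 as well and 932 with 1 surrogate variable. DESeq2 gave 1 lower gene (Gabrr2) with either filtering. Adjusted p under 0.10 and a fold change limit of 0.5 also gave 0. The cause was not tested for any change below, except where stated. Windows of 60 or 120 rows gave 1 lower gene in register. In register, lower genes were 2 with DESeq2 under either filtering and with 1 surrogate variable (Gabrr2, Abca1), 0 adjusted over all tested rows, where more rows are tested, and 0 to 2 with 1 library left out. Gabrr2 adjusted in register was 0.0628 without aCSF 4 and 0.0534 without aCSF 6; 2 lower genes appeared without aCSF 1, L-fucose 5 or L-fucose 6. Higher genes in register were 1 (Penk) with 1 surrogate variable, without aCSF 5 and 6, and without these and L-fucose 4.

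The replicate numbers did not pair the libraries: same-numbered libraries correlated at -0.17 to 0.17 with 1 of 6 pairs over 0.1, 2 libraries correlated best with their own number, and 2 numbers differed in Y-linked rows. With the replicate block, edgeR and limma gave 0 genes over all rows and 0 lower genes in register (Gabrr2 0.0574 and 0.0652). DESeq2 with the replicate block kept Gabrr2 in register (0.00407) and lost it over all rows (0.0528 against 0.003114 without the block; log2 fold change -1.55 against -1.63). Over all rows it gave 0 higher and 1 lower gene, the row labelled F830045P16Rik, or 2 higher and 6 lower with filtering at 0.1, Gabrr2 and mt-Atp6 among them. The block changed no list call.

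List calls were 0 to 1 with 1 library left out, the call being oligodendrocytes without aCSF 4 (0.0379; 0.302 with an estimated correlation), 1 without aCSF 5 and 6 and 1 without these and L-fucose 4. Both of the latter were the mitochondrial list, higher, at 9.77e-05 and 2.60e-05 (adjusted p = 0.879 and 0.906 with an estimated correlation), with 13 of 13 positive and medians of 0.34. Both fits leave out the aCSF libraries with the highest mitochondrial shares, which by itself moves this list up. With 1 library left out the adjusted p of this list ran from 0.379 to 0.993 and its direction turned without aCSF 1, aCSF 4 or L-fucose 6. The oligodendrocyte list ran from 0.0379 to 0.702. The fucose list turned without the 3 libraries (0.984).

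Of 1761 fold changes of the 59 named genes under 30 alternatives, 1710 kept direction and side of the threshold, 5 newly passed and 46, of 14 genes, turned sign. Without aCSF 5 and 6, values were 0.094 for mt-Nd5, 0.037 for Kcnd2, 0.036 for Sema5a, 0.056 for Asns, -0.0083 for Fut1 and -0.66 for Fuom. Without L-fucose 4 as well, they were 0.14 for mt-Nd5, 0.071 for Kcnd2, 0.085 for Sema5a, 0.067 for Asns, -0.84 for Fuom and 0.015 for Fut9. Asns was 0.0068 with upper-quartile factors and 0.0099 with 1 surrogate variable. Fuom, a row with a mean of 15.7, was -0.13 with DESeq2 under either filtering, -0.14 with RLE or TMM and -0.12 with upper-quartile factors, -0.026 with the replicate block in edgeR, -0.050 with the surrogate variable and -0.042 with a pseudocount of 5. With 1 library left out, ranges were -0.16 to 0.11 for Fut7, -0.066 to 0.14 for Slc35c2, -0.10 to 0.45 for Fut1, -0.61 to 0.54 for Fuom, -0.33 to 0.018 for Pofut2, -0.026 to 0.063 for Gabbr2, -0.015 to 0.15 for Cox6c, -0.041 to 0.038 for Asns, -0.27 to 0.0023 for Ddx58 and -0.074 to 0.17 for Foxp2.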

Other observations

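The thinning test and the test of further cilium genes were set before their results were seen, as were the counts over other splits of the libraries for rows at an unadjusted p under 0.05 and for rows in register. The counts over other splits for rows past the adjusted threshold and for lists were set after. Among genes in register, those most abundant in the sections included Rab2a, a small GTPase of vesicle traffic between the endoplasmic reticulum and the Golgi, at a mean of 11250 ± 1103 normalized reads (SD over 12 libraries), Ank, a membrane transporter of pyrophosphate, at 7567 ± 597 and Ctnnd2, a catenin of dendritic junctions, at 7559 ± 494. Penk varied more, at 7615 ± 2490.

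Spef2, Cfap206 and Capsl were among the lowest p in register, and the hypothesis was that RNA of cilium genes is lower after L-fucose. Of 6 further cilium genes listed, 4 were tested in register: Ccdc180 at -0.23, Ropn1l at 0.21, Rgs22 at -0.62 and Spag1 at -0.04. That none of them was among the lowest p was known when the list was written. Their median log2 fold change was -0.1337 (exact permutation p = 0.574 for their mean, n = 6 each), which neither reached the bound set for a shared decrease nor excluded one, with 4 genes too few to decide.

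aCSF 5 and 6 had the fewest rows above 0. Fewer reads outside the mitochondrial genome as the cause is argued against: after thinning every library to 6082064 such reads, the higher of them was still 9.613% below the lowest of the other 10, at 14220 and 14799 rows against 16373 or more. A difference in the tissue sampled or in RNA quality stays open as untested, since the labels give neither region nor RNA integrity.

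Splits of the 12 libraries into 6 and 6, 100 drawn from 462 with the real one included, gave the following. For rows at an unadjusted p under 0.05, 24 splits had at least the real 643, with 1748 the highest of the others, so chance could not be excluded. For rows past the adjusted limma threshold, all 100 reached the real 0, which any split does, so this count tests nothing, and the highest other had 9. For lists past the camera threshold, all 100 likewise had to reach the real 0. The highest other had 2, and 35 splits had a list past it, so a list past this threshold would not by itself exclude chance. For rows in register adjusted over these alone, 4 splits had at least the real 1 (Gabrr2), with 5 the highest of the others. Chance is not excluded by this: the share lies just under 0.05 in a draw of splits, the adjustment was added after the data were seen, a choice that the splits do not repeat, and the call ended without aCSF 4 (adjusted p 0.0628) and without aCSF 6 (0.0534).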
